A study of Xenopus tropicalis with 15 samples.

How the data were processed

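Total RNA from tail tissue of 15 samples of wild-type Xenopus tropicalis tadpoles was measured, 3 samples in each of 5 groups. Per the labels' protocols, RNA was taken by phenol:chloroform with DNaseI treatment and libraries were made with a NEBNext Ultra kit for paired-end sequencing on an Illumina HiSeq. Samples were grouped by their titles. The treatment field of the IWR samples counts up from IWR-1 with the replicate, while the study's design names IWR-1 alone, so all 3 were taken as IWR-1. The 0 hpa samples were untreated, so DMSO, time and position along the tail differ together between 0 hpa and 24 hpa.

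Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.6.5 and quantified them with kallisto, then used edgeR. The versions of kallisto and edgeR and the genome build are not given in the sources used here. The deposited estimated counts are kallisto's assignment of reads to 1 transcript per gene model, per the file headers, and 21.4% of them differ from a whole number by more than 1e-06. The deposited TPM values divide these by the effective length and scale each library to the same sum, per the file headers, and they were not used in the tests. The effective length, deposited beside them, entered 1 alternative as an offset. The deposited CPM table of the authors holds 15892 gene models, whose values equal the estimated counts times a constant per library and have the same sum in each, so no factor such as TMM is in them. It holds every model above 0.5 CPM in at least 14 libraries and none above it in 10 or fewer. Of the tested models, 2931 lie outside it. Gene names are those of the files. A reference table for the UCB_Xtro_10.0 assembly was used for names and synonyms only. Of 1334 symbols in the gene lists 1236 were found, 33 of them through that table. In the files 4671 models share a symbol with another, and 15266 carry a placeholder name. Near-identical copies, such as globins and keratins, can exchange reads in the counting, so their single values are uncertain.

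Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. All 15 libraries were fitted together with 1 coefficient per group, TMM factors, the filter of filterByExpr (minimum count 10, total 15) and the quasi-likelihood F test, with a common biological coefficient of variation of 0.0936 and 10 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method in each comparison and called under 0.05. The comparisons were DMSO at 24 hpa against 0 hpa, each compound against DMSO, and the compounds against each other. Standard errors of log2 ratios come from the fitted F statistic. A set of 38 gene lists was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01. The same test with the correlation estimated per list, and the rotation test fry, are given beside it. Camera asks whether a list moved more than the other genes and fry whether it moved at all, so ranges of a list's adjusted p over its alternatives are those of camera, and fry's value is given apart. Ribosomal protein genes, 80 models by symbol of which 79 were tested, formed a test of their own. They include the related rpl7l1, rps19bp1, rpl22l1 and rps27l. Members were counted as higher or lower by the gene test, and again with the adjustment run over the list's members alone. Tables and drawings were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

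The comparisons, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. Named genes are the 8 largest rises and 8 largest falls of each comparison against 0 hpa or DMSO (5 and 5 between compounds) among called models with at least 5 CPM in 1 group, no overlap between the groups and a name that is no placeholder, up to 4 list members with the smallest adjusted p, and hif1a, epas1, arnt, ctnnb1, axin2 and lef1. Clone-numbered names such as mgc108322 were counted as names. Some genes that the rule names are not reported here. Each gene named for the size of its change is therefore shifted in the same direction in 3 of 3 libraries. For a group with 0 counts a ratio is a bound against 3 counts over the group, and for 1 to 3 counts it is given with its counting interval at a level of 0.95.

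The alternatives were RLE and upper-quartile factors, no filter on low counts, a filter on a mean of 10 counts, DESeq2 1.42.0, only the 2 groups compared, replicate number as a block, an offset of effective length, limma on log2(CPM + 1) of the deposited table, a threshold of 2-fold, the other list tests and leaving out each library in turn. Counting against library size only, with no scaling factor, was added after the data were seen. It moved the median log2 ratio of all genes by 0.136, 0.143 and 0.155 for 2ME, echinomycin and IWR-1, and upper-quartile factors moved that of echinomycin by 0.102. TMM factors were 0.909 to 0.961 at 0 hpa, 0.913 to 0.959 with DMSO and 1.03 to 1.071 with the compounds. Overlaps were set against 20 simulated sets of unchanged groups that share their controls. The tests were also tested on simulated data, with counts drawn around the means of the real libraries and genes changed by known ratios. No library was left out of the main tests.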

Results

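Tail tissue of Xenopus tropicalis tadpoles was profiled by paired-end RNA sequencing of total RNA in 15 libraries, 3 in each of 5 groups. Wild-type tadpoles lost the posterior part of the tail at NF stage 41, 3 days after fertilisation. The 0 hpa (hours post amputation) group was untreated tissue from about 250 µm anterior to the amputation plane. The other groups were about 250 µm of regenerating tissue at 24 hpa, after rearing at 23 °C with 0.1% DMSO, 5 µM 2-methoxyestradiol (2ME), 0.5 µM echinomycin or 10 µM IWR-1. 2ME is an oestradiol metabolite that binds tubulin and lowers HIF1A protein, echinomycin is a DNA-binding antibiotic that blocks HIF1 from its sites, and IWR-1 is a tankyrase inhibitor that stabilises Axin and lowers Wnt signalling. The total of estimated counts per library ranged from 17.3 to 23.4 M. A count of 0 therefore allowed up to 0.128 to 0.173 CPM (3 counts) per library, and such floors and the intervals given for ratios cover counting error only. Of the gene models given, 18823 had enough counts to be tested. The p-values measure only the spread between these samples, since the labels do not say what a replicate number stands for. Log2 ratios are given ± SE and CPM as mean ± SD with n = 3 per group throughout.

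The libraries grouped by condition. The first principal component of log2 CPM, which held 48.5% of the variance, parted the 0 hpa libraries (-105 to -104.3) from all 24 hpa libraries (2.2 to 45.8). The second held 16.3% and parted the echinomycin libraries (-58.9 to -45.6) from the rest. Correlations of log2 CPM between libraries of a group, taken across genes, which are not independent replicates, were 0.9903 to 0.9954.

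**Figure D1:**
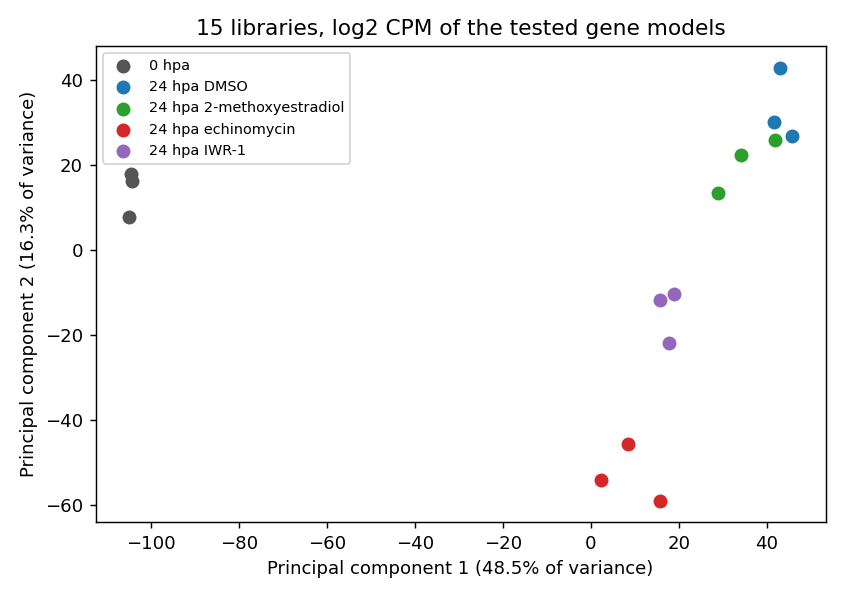
Scores of the 15 libraries on the first and second principal components of log2 CPM (48.5% and 16.3% of the variance, arbitrary units), coloured by group, each point 1 library. The 3 libraries at 0 hpa lie at -105 to -104.3 on the horizontal axis and the echinomycin libraries at -58.9 to -45.6 on the vertical axis.

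The comparison of DMSO-treated regenerating tissue at 24 hpa with tail tissue at 0 hpa asks what changes in a tail regenerating without an antagonist. Most of the listed genes of muscle, blood, vessels, nerve and pigment cells were lower in the regenerating tissue, and immediate early, leukocyte and ribosome assembly genes were higher. Of the 18823 gene models, 11854 changed (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 6056 higher and 5798 lower, and 4372 of these by 2-fold or more (1651 higher and 2721 lower). That balance depends on the scaling, with 5785 and 6006 for RLE and 5136 and 6595 for upper-quartile factors. In 11402 of the called models all libraries of one group lay above all of the other; 66.8% of all tested models showed such a separation, against 10% by chance.

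The largest rises included keratin and protease genes, which were not tested as lists. The collagenase mmp13l rose from 0.223 ± 0.107 to 398 ± 41.2 CPM (log2 ratio 10.81 ± 0.33), the gelatinase mmp9.2 from 0.525 ± 0.292 to 206 ± 30.1 CPM (8.64 ± 0.39), and the keratin krt18.2 from 0.463 ± 0.26 to 153 ± 34.2 CPM (8.38 ± 0.27). The serine protease gene prss8l100494289 rose from 0.0848 ± 0.147 to 22.1 ± 4.95 CPM (8.04 ± 0.55). Keratin krt51 and the collagenase mmp8 had 0 counts at 0 hpa and were at least 246-fold and at least 193-fold higher at 24 hpa (against a floor of 3 counts over the group), reaching 14.6 ± 1.12 and 11.2 ± 2.97 CPM. Keratin krt53, with 1 count at 0 hpa, was 307 times higher (counting interval 54.8 to 12200). The largest falls included globin and muscle genes. Globin hbe1 fell from 1880.0 ± 1523 to 24.9 ± 7.17 CPM (-6.24 ± 0.52), hba-l4 from 1489 ± 1203 to 23 ± 5.87 CPM (-6.02 ± 0.51) and hbz from 896 ± 699 to 7.2 ± 1.63 CPM (-6.97 ± 0.54). Globins hba-l2, hba2 and hba1 fell too, with log2 ratios of -6.71, -6.59 and -6.39. The muscle ankyrin repeat gene ankrd2 fell from 129 ± 10.3 to 1.32 ± 0.187 CPM (-6.61 ± 0.21) and mlip, a nuclear lamina partner in muscle, from 9.34 ± 0.482 to 0.11 ± 0.15 CPM (-6.47 ± 0.51). Globin levels varied widely between the 0 hpa libraries, and near-identical globin and keratin copies share reads, so values of single copies are uncertain.

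Muscle, blood, vessel, nerve and pigment genes fell together. Among genes of striated muscle, 41 of the 46 members fell, 1 rose and 4 did not pass (41 fell and 1 rose adjusted over the list alone), with a median log2 ratio of -3.37 (adjusted p = 2.68e-19, and adjusted p = 0.165 with an estimated correlation). The cardiac actin gene actc1 fell (log2 ratio -3.44), the troponin gene tnni2 (-3.83), the fast myosin light chain gene mylpf (-3.53) and calsequestrin casq1 (-3.51). In the erythroid list, all 27 genes fell (27 fell adjusted over the list alone), with a median of -4.41 (adjusted p = 3.85e-09, and adjusted p = 0.329 with an estimated correlation). For endothelium, 25 of the 30 genes fell, 1 rose and 4 did not pass (26 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.89e-08, and adjusted p = 0.137 with an estimated correlation). The apelin receptor aplnr was at -2.56 ± 0.15 and von Willebrand factor vwf at -1.85 ± 0.11. Of neural progenitor genes, 24 of the 27 members fell and 3 did not pass (24 fell adjusted over the list alone), with a median of -1.86 and examples in the lipid carrier fabp7 (-3.13 ± 0.21) and the Notch effector hes5.1 (-5.59 ± 0.38). This was the one list of the comparison whose call held with an estimated correlation (adjusted p = 4.09e-08, and adjusted p = 0.0241 with an estimated correlation). Among neuronal genes, 35 of the 47 members fell, 4 rose and 8 did not pass (35 fell and 4 rose adjusted over the list alone, camera adjusted p = 2.28e-07, and adjusted p = 0.165 with an estimated correlation). Synaptotagmin syt1 was at -3.14 ± 0.26. The most abundant neuronal genes with DMSO, picked after their values were seen, did not fall on average (dpysl3 69.6 to 77.8, mapt 64.7 to 72 and stmn2 49.3 to 61.2 CPM). For melanophores and neural crest, 16 of the 22 genes fell, 3 rose and 3 did not pass (16 fell and 3 rose adjusted over the list alone, camera adjusted p = 2.19e-05, and adjusted p = 0.137 with an estimated correlation). The pigment enzymes dct and tyr were at -3.95 ± 0.14 and -3.76 ± 0.18. Glycolytic genes fell as well, 15 of 20 lower and 4 higher (15 and 4 adjusted over the list alone; adjusted p = 7.10e-06, and adjusted p = 0.158 with an estimated correlation). Aldoc, an aldolase, was at -3.45 ± 0.11 and the monocarboxylate transporter slc16a3 at -2.2 ± 0.091.

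Ribosome assembly genes rose while mitotic genes fell. In the ribosome biogenesis list, all 52 genes rose (52 rose adjusted over the list alone), with a median of 0.89 (adjusted p = 2.49e-20, and adjusted p = 0.144 with an estimated correlation). The nucleolar genes imp4 and nop58 rose by 1.45 and 1.22 on the log2 scale. Of ribosomal protein genes, all 79 tested rose (79 rose adjusted over the list alone), with a median of 0.47 (adjusted p = 2.13e-15 as the only set in its test, and adjusted p = 0.245 with an estimated correlation), and their share of counts went from 6.24 to 7.12% at 0 hpa to 8.58 to 9.69% with DMSO. Among genes of G2 and mitosis, 47 of the 53 members fell, 1 rose and 5 did not pass (47 fell and 1 rose adjusted over the list alone), with a median of -0.58 (adjusted p = 1.31e-09, and adjusted p = 0.406 with an estimated correlation). The kinetochore gene cenpf fell (-1.11) and the checkpoint kinase ttk (-0.86). Immediate early and AP-1 genes moved up, as 26 of the 30 members rose, 2 fell and 2 did not pass (26 rose and 2 fell adjusted over the list alone, camera adjusted p = 5.16e-08, and adjusted p = 0.165 with an estimated correlation). The nuclear receptor nr4a2 was at 2.63 ± 0.12 and junb, a subunit of AP-1, at 2.36 ± 0.12. For leukocytes, 33 of the 40 genes rose, 2 fell and 5 did not pass (33 rose and 2 fell adjusted over the list alone, camera adjusted p = 8.02e-08, and adjusted p = 0.165 with an estimated correlation). The granulocyte receptor csf3r was at 2.19 ± 0.12 and myeloperoxidase mpo at 1.86 ± 0.10. Among inflammation genes, 20 of the 30 members rose, 2 fell and 8 did not pass (20 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000294, and adjusted p = 0.137 with an estimated correlation). The cytokine inhibitor socs3 was at 3.18 ± 0.10 and complement c3 at 2.7 ± 0.10. In the matrix list, 38 of the 56 genes fell, 13 rose and 5 did not pass (39 fell and 13 rose adjusted over the list alone), with a median of -0.79 (adjusted p = 6.21e-05, and adjusted p = 0.323 with an estimated correlation). Fibronectin fn1 rose by 4.06 while periostin postn fell (-1.96). Epidermal genes were higher in 16 of 31 and lower in 7 (16 and 7 adjusted over the list alone; adjusted p = 0.0367, and adjusted p = 0.165 with an estimated correlation). Krt18.1 was at 2.27 ± 0.086.

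Among patterning genes, 12 of the 16 posterior hox genes (paralogs 9 to 13) rose, 3 fell and 1 did not pass (12 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.00132, and adjusted p = 0.388 with an estimated correlation). Hoxa9 was at 1.51 ± 0.066 and hoxc10 at 1.34 ± 0.13. Of central hox genes (paralogs 5 to 8), 7 of the 11 members rose and 4 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.0486, and adjusted p = 0.165 with an estimated correlation). Hoxa7 was at 1.3 ± 0.089. In the Wnt target list, 14 of the 24 genes rose, 4 fell and 6 did not pass (14 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0486, and adjusted p = 0.457 with an estimated correlation). The transcription factor gene cdx2 rose by 2.2 and the Wnt inhibitor wif1 fell (-3.35). Beta-catenin ctnnb1, which carries the canonical Wnt signal, rose from 692 ± 18.5 to 1416 ± 45.4 CPM (1.03 ± 0.050), the feedback gene axin2 from 40.7 ± 3.39 to 57.4 ± 5.33 CPM (0.50 ± 0.075) and the Wnt transcription factor lef1 from 28.2 ± 2.41 to 74.8 ± 11 CPM (1.4 ± 0.13). The tailbud list did not pass as a set (adjusted p = 0.208, 0.148 to 0.545 over its alternatives, fry adjusted p = 3.81e-05), while 13 of the 25 members rose, 6 fell and 6 did not pass (13 rose and 6 fell adjusted over the list alone). The pluripotency factor sall4 was at 2.44 ± 0.083. Nor did the FGF list (adjusted p = 0.373, 0.303 to 0.660, fry adjusted p = 0.00383), in which 11 of the 24 genes rose, 7 fell and 6 did not pass (11 rose and 7 fell adjusted over the list alone) and the ligands fgf20 and fgf16 rose by 4.78 and 3.42. HIF1 targets moved both ways: 18 of the 41 members fell, 14 rose and 9 did not pass (18 fell and 16 rose adjusted over the list alone, camera adjusted p = 0.627). The hormone stc1 was at 6.95 ± 0.31 and lysyl oxidase lox at -3.81 ± 0.16. The HIF subunit gene epas1 fell from 50.8 ± 7.85 to 11.1 ± 0.98 CPM (-2.2 ± 0.14). For hif1a the log2 ratio was -0.003 ± 0.054 (adjusted p = 0.970), a sign that turned to 0.013 without a scaling factor, and for arnt, the HIF partner, 0.14 ± 0.060 (adjusted p = 0.0537, ranging from 0.0438 to 0.510 over its alternatives).

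The adjusted p of the genes named as changed was at most 1.99e-05, and 22 of the 38 lists were called, 10 up and 12 down. Other splits of these libraries into groups of 3 called 9 to 22 lists. Time after amputation, position along the tail and DMSO all differ between 0 hpa and 24 hpa, so the comparison does not separate them. The calls of the epidermis, Wnt target and central hox lists ended when some libraries were left out: epidermis without 0 hpa replicate 1 (adjusted p = 0.0616) or DMSO replicate 3 (adjusted p = 0.0700; 0.0163 to 0.165 over all its alternatives), Wnt targets without 0 hpa replicate 1 (adjusted p = 0.0988; 0.0267 to 0.457) and central hox without 0 hpa replicate 3 (adjusted p = 0.0567) or DMSO replicate 2 (adjusted p = 0.0676; 0.0333 to 0.165).

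**Figure D2:**
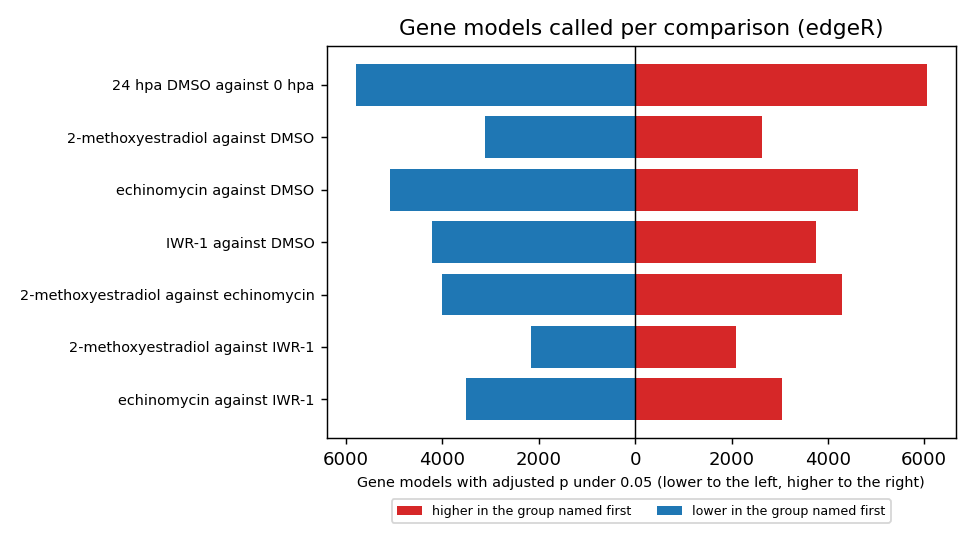
Number of gene models called higher or lower (adjusted p under 0.05, edgeR) in the 7 comparisons, with higher to the right of 0 in red and lower to the left in blue. Regeneration has 6056 higher and 5798 lower, echinomycin 4631 and 5078, and without a scaling factor the compound bars would read 4550 and 1598 (2ME), 6315 and 3441 (echinomycin) and 5715 and 2296 (IWR-1).

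With 2ME the question is what an antagonist of Hif1a changes in regenerating tissue against DMSO. Camera called the drug metabolism, p53 and muscle lists higher and the leukocyte, neuron, tubulin, DNA replication, hox and ribosomal protein lists lower, none of them with an estimated correlation. The test called 5749 gene models, 2634 higher and 3115 lower, of which 874 changed by 2-fold or more (461 higher and 413 lower); 5507 showed no overlap between the groups, and 45.2% of all tested models did, against 10% by chance.

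The genes with the largest rises were mgc108322, from 7.59 ± 2.01 to 182 ± 19.9 CPM (log2 ratio 4.59 ± 0.16), and the p53-induced TNF receptor gene eda2r, from 3.56 ± 0.414 to 27.1 ± 1.34 CPM (2.92 ± 0.17). The cell adhesion gene dscaml1 rose by 2.56 on the log2 scale, the oxidative stress gene osgin1 by 2.55, aifm3-like by 2.62 and xbg100491922 by 2.31. The cytochrome P450 genes cyp2e1 and cyp4b1 rose from 3.54 ± 0.557 to 18.2 ± 1.08 CPM and 14.1 ± 1.5 to 64.6 ± 1.34 CPM. The immediate early gene fos fell from 156 ± 11.6 to 26 ± 9.18 CPM (-2.58 ± 0.23), the nuclear receptor nr4a2 from 46.7 ± 3.46 to 13.2 ± 0.724 CPM (-1.83 ± 0.11) and the chemokine cxcl11 from 6.71 ± 2.08 to 0.64 ± 0.13 CPM (-3.37 ± 0.42). The G protein regulator rgs1 fell (-2.17), fucolectinloc100491211 (-2.12), MGC147302 (-1.83) and the flow-responsive factor klf2 (-1.83). The cell cycle inhibitor cdkn2d (gene10649) fell (-4.09) from a mean whose SD was nearly as large (7.35 ± 6.85 to 0.441 ± 0.763 CPM); without DMSO replicate 2 its log2 ratio was -3.02 (adjusted p = 0.0742), and its adjusted p ranged from 0.000573 to 0.228 over its alternatives.

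Of the HIF subunit genes, hif1a rose from 227 ± 9.21 to 270.1 ± 5.1 CPM (0.25 ± 0.054), epas1 from 11.1 ± 0.98 to 21.6 ± 0.133 CPM (0.96 ± 0.14) and arnt from 63.7 ± 3.36 to 73.6 ± 5.13 CPM (0.21 ± 0.059). In the list of HIF pathway components, which was not called (adjusted p = 0.107; fry adjusted p = 0.00296), 5 of the 12 genes rose, 1 fell and 6 did not pass (5 rose and 1 fell adjusted over the list alone). The HIF1 target list was not called either (adjusted p = 0.776). In it, 8 of the 41 members rose, 5 fell and 28 did not pass (8 rose and 5 fell adjusted over the list alone). The mitochondrial gene higd1a was at 0.64 ± 0.061 and the mTOR inhibitor ddit4 at -0.62 ± 0.090. The median was -0.061 although the test leaned upward. It became 0.080 without a scaling factor, and the test turned downward without DMSO replicate 2 (adjusted p = 0.951). Of Wnt targets, 5 of the 24 genes rose, 3 fell and 16 did not pass (5 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.498). The zinc finger gene sp8 was at 0.70 ± 0.14. Axin2 fell from 57.4 ± 5.33 to 49.4 ± 1.66 CPM (-0.22 ± 0.073, adjusted p = 0.0319; without DMSO replicate 2 the log2 ratio was -0.13, and its adjusted p ranged from 0.0139 to 0.469 over its alternatives). The values for ctnnb1 and lef1 were 0.10 ± 0.049 (adjusted p = 0.130, ranging from 0.00187 to 0.265) and 0.27 ± 0.12 (adjusted p = 0.0873, ranging from 0.0198 to 0.302).

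Among genes of xenobiotic and steroid metabolism, 9 of the 24 members rose, 1 fell and 14 did not pass (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000413, and adjusted p = 0.162 with an estimated correlation), among them the glutathione transferase gstp1 (1.9 ± 0.093), the sulfotransferase sult1a1 (1.36 ± 0.12) and the efflux pump abcg2 (1.06 ± 0.088). In the p53 list, 11 of the 43 genes rose, 5 fell and 27 did not pass (11 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.0487, and adjusted p = 0.265 with an estimated correlation). Beside eda2r these included mdm2, which degrades p53, at 1.44 ± 0.087 and the cyclin ccng1 at 1.13 ± 0.088. Muscle genes rose, 28 of 46 with a median of 0.62 (28 rose and 2 fell adjusted over the list alone; adjusted p = 1.58e-06, and adjusted p = 0.550 with an estimated correlation). Actc1 rose from 484 ± 64.9 to 790.0 ± 184 CPM and the myosin myh2 was at 1.02 ± 0.21. The libraries differed: ckm stood at 518.6 and 547.9 CPM in 2ME replicates 1 and 2 and at 323.8 in replicate 3, against 233.9 to 311.6 with DMSO, and the muscle share of the distance to 0 hpa was 0.073, 0.067 and 0.007. Of leukocyte genes, 22 of the 40 members fell and 18 did not pass (23 fell adjusted over the list alone), with a median of -0.56 (adjusted p = 2.36e-07, and adjusted p = 0.265 with an estimated correlation). The macrophage receptor csf1r fell (-1.09) and mpo (-1.07). In the neuron list, 22 of the 47 members fell and 25 did not pass (22 fell adjusted over the list alone, camera adjusted p = 7.49e-05, and adjusted p = 0.363 with an estimated correlation). The growth cone gene dpysl3 was at -1.04 ± 0.076 and vamp2, a synaptic vesicle protein, at -1.13 ± 0.13. For tubulins, the family 2ME binds as protein, 11 of the 19 genes fell, 1 rose and 7 did not pass (13 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.000388, and adjusted p = 0.265 with an estimated correlation). Tuba1a was at -0.75 ± 0.095 and tuba1b at -0.63 ± 0.075. In the S phase list, 26 of the 41 genes fell, 1 rose and 14 did not pass (31 fell and 1 rose adjusted over the list alone, camera adjusted p = 3.97e-08, and adjusted p = 0.476 with an estimated correlation). The thymidine kinase tk1 was at -0.67 ± 0.11 and the chromatin assembly gene chaf1a at -0.70 ± 0.10. The S phase counts were 1 higher and 9 lower without a scaling factor. The G2 and mitosis list was not called (adjusted p = 0.568), and 6 of the 53 members fell, 3 rose and 44 did not pass (6 fell and 2 rose adjusted over the list alone), a balance that turned to 14 higher and 2 lower without a scaling factor. The immediate early list was called lower, and 12 of the 30 members fell, 5 rose and 13 did not pass (12 fell and 5 rose adjusted over the list alone, camera adjusted p = 0.0426, and adjusted p = 0.681 with an estimated correlation), or 7 higher and 8 lower without a scaling factor.

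Hox and ribosomal protein genes fell. Of posterior hox genes, 12 of the 16 members fell and 4 did not pass (13 fell adjusted over the list alone), with a median of -0.56 (adjusted p = 2.75e-07, and adjusted p = 0.265 with an estimated correlation). Hoxc10 was at -1.15 ± 0.12 and hoxa9 at -0.55 ± 0.063. For central hox, 8 of the 11 genes fell and 3 did not pass (9 fell adjusted over the list alone, camera adjusted p = 0.000388, and adjusted p = 0.129 with an estimated correlation). Hoxa7 was at -0.72 ± 0.085. Central hox counts were 0 higher and 5 lower without a scaling factor. Ribosomal protein genes fell in 78 of 79 (78 fell adjusted over the list alone), with a median of -0.42 (adjusted p = 1.19e-31, and adjusted p = 0.0981 with an estimated correlation) and a share of counts of 7.28 to 7.73%, against 8.58 to 9.69% with DMSO. Named genes called changed had an adjusted p of at most 0.0319, and 15 of the 38 lists were called, 6 up and 9 down. Other splits of these libraries into groups of 3 called 5 to 13 lists. With an estimated correlation camera called 0 lists (6 at an unadjusted p under 0.05), and fry called 19. Without DMSO replicate 2 the number of called gene models was 3766. Without a scaling factor the calls split into 4550 higher and 1598 lower, and limma on the deposited CPM gave 75.4% higher. The p53 call ended without DMSO replicate 1, 2ME replicate 2 or 2ME replicate 3 (adjusted p = 0.0649, 0.0506 and 0.0601; 0.0252 to 0.265 over its alternatives), that of the immediate early genes without DMSO replicate 3 or 2ME replicate 3 (adjusted p = 0.140 and 0.0590; 0.00684 to 0.681), and that of arnt without DMSO replicate 2 (adjusted p = 0.0550), 2ME replicate 1 (0.0536) or 2ME replicate 3 (0.0744; 0.000639 to 0.0744).

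**Figure D3:**
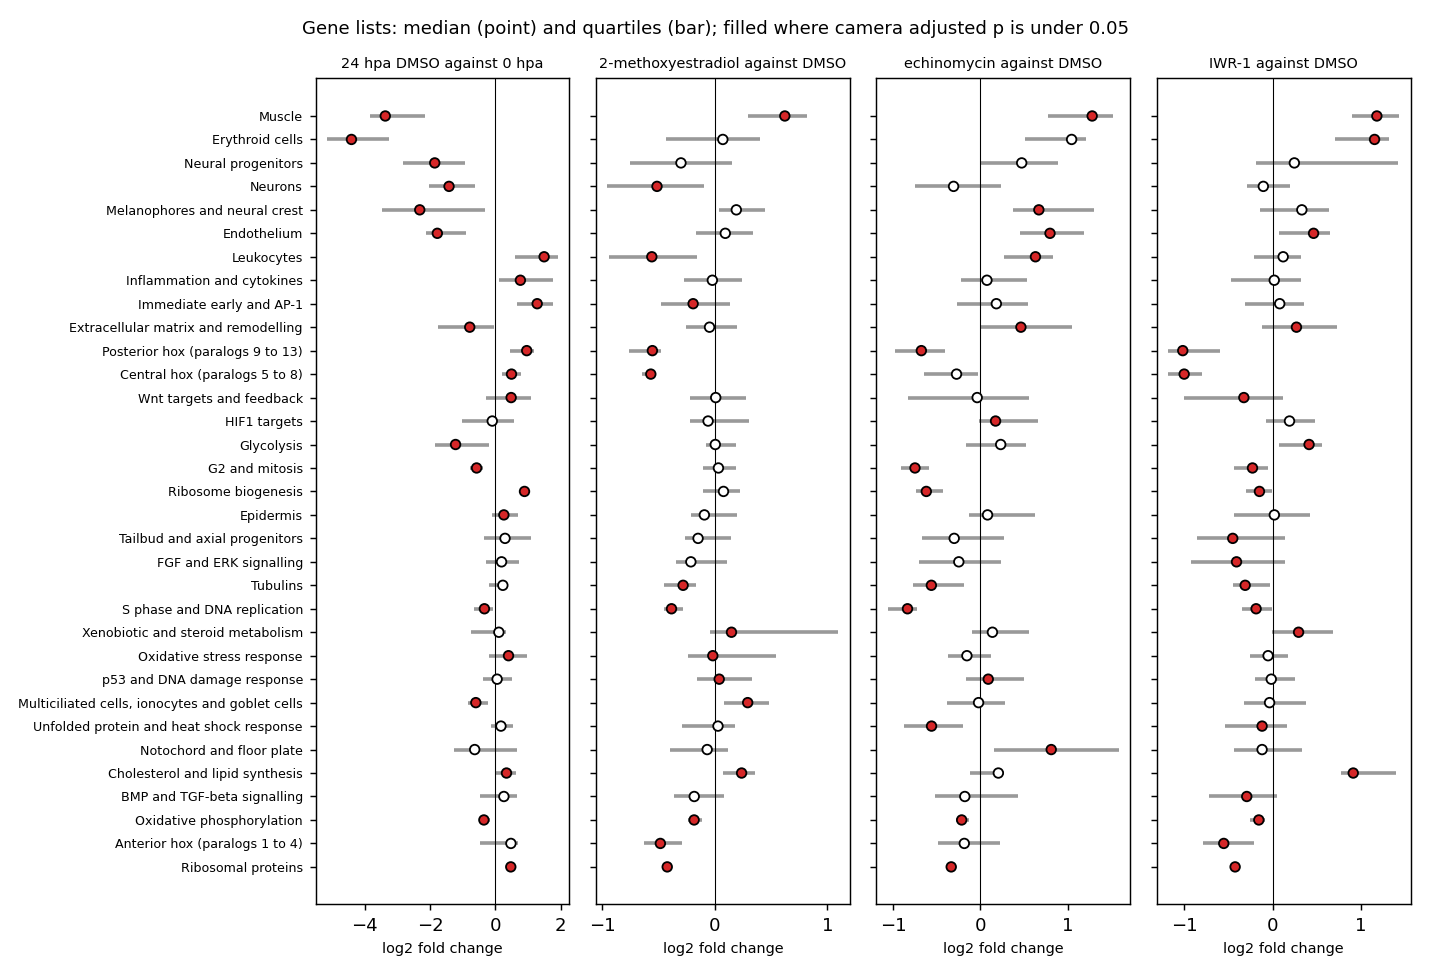
Median log2 ratio (points) and quartiles (bars) of the members of 33 gene lists in the 4 comparisons against 0 hpa or DMSO, filled red where camera gave an adjusted p under 0.05 with its preset correlation. Posterior hox genes have medians of 0.96 at 24 hpa and of -0.56, -0.68 and -1.02 with 2ME, echinomycin and IWR-1, with no change of sign under any scaling, while some medians, such as those of IWR-1 for neurons, oxidative phosphorylation, ribosome biogenesis and unfolded protein genes turn positive without a scaling factor.

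Echinomycin, the second compound given as an antagonist of Hif1a, was compared with DMSO. Most listed genes of mitosis, DNA replication, ribosome assembly and protein folding fell, while most of muscle, notochord, matrix, leukocytes, endothelium and pigment cells rose, though no list was called with an estimated correlation. The test called 9709 gene models, 4631 higher and 5078 lower; by 2-fold or more, 1662 were higher and 597 lower. No overlap between the groups was seen in 9181 called models and in 57.2% of all tested models, against 10% by chance.

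Dscaml1 rose from 2.6 ± 0.348 to 34.7 ± 7.91 CPM (log2 ratio 3.73 ± 0.16), the p53-induced receptor eda2r from 3.56 ± 0.414 to 40.3 ± 8.87 CPM (3.49 ± 0.17), otos from 2.98 ± 0.763 to 36.5 ± 13.7 CPM (3.6 ± 0.31) and pdgfrl.2 from 4.71 ± 0.769 to 52.8 ± 12.9 CPM (3.49 ± 0.18). The adaptor gene sh2d6 rose by 3.42, the anti-proliferative btg5.3 by 3.72 and the otoferlin gene otof by 3.37. Fndc7 rose from 0.537 ± 0.492 to 6.77 ± 7.76 CPM (3.7 ± 0.82), with an SD larger than its mean. The keratin genes krt51 and krt53 nearly disappeared. Krt51 had 3 counts over the group and was 312 times lower than with DMSO (counting interval 107 to 1520), and krt53 had 2 counts and was 195 times lower (53.6 to 1620). The hormone gene stc1, a HIF1 target, fell from 49.5 ± 13.9 to 5.07 ± 1.29 CPM (-3.28 ± 0.20), the endopeptidase ecel1 from 7.04 ± 0.655 to 0.748 ± 0.468 CPM (-3.23 ± 0.28), the retinol acyltransferase lrat from 9.59 ± 2.25 to 1.8 ± 0.543 CPM (-2.41 ± 0.24), MGC79725 from 209 ± 34.5 to 39.4 ± 9.26 CPM (-2.41 ± 0.18) and aif1l from 32.4 ± 2.92 to 6.26 ± 2.32 CPM (-2.37 ± 0.21). Cdkn2d (gene10649) fell from 7.35 ± 6.85 to 0.16 ± 0.276 CPM (-5.4 ± 1.21; without DMSO replicate 2 -4.34, without echinomycin replicate 2 -10.26; DESeq2 adjusted p = 0.0600, and 4.48e-05 to 0.0600 over its alternatives).

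The HIF1 target list moved up with echinomycin: 17 of the 41 members rose, 5 fell and 19 did not pass (17 rose and 5 fell adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0101, and adjusted p = 0.234 with an estimated correlation). Members went both ways, with lox at 1.78 ± 0.15, against stc1 and higd1a (-1.08 ± 0.063). Epas1 rose from 11.1 ± 0.98 to 20.7 ± 4.78 CPM (0.90 ± 0.14). For hif1a the log2 ratio was 0.060 ± 0.054 (adjusted p = 0.369, ranging from 0.00619 to 0.609 over its alternatives) and for arnt 0.12 ± 0.060 (adjusted p = 0.109, ranging from 0.00196 to 0.257; without DMSO replicate 3 adjusted p = 0.0309). Among named Wnt genes, ctnnb1 fell from 1416 ± 45.4 to 1128 ± 37.8 CPM (-0.33 ± 0.049), axin2 from 57.4 ± 5.33 to 35.9 ± 1.12 CPM (-0.68 ± 0.074) and lef1 from 74.8 ± 11 to 52.5 ± 9.83 CPM (-0.51 ± 0.12). The Wnt target list as a set was not called (adjusted p = 0.609, 0.436 to 0.826 over its alternatives, fry adjusted p = 0.00575). In it, 11 of the 24 genes fell, 10 rose and 3 did not pass (11 fell and 10 rose adjusted over the list alone), the ligand fgf8 at -2.27 ± 0.17 and wif1 at 2.14 ± 0.12, and its median of -0.037 became 0.068 with upper-quartile factors and 0.11 without a factor.

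Proliferation and growth genes fell. In the G2 and mitosis list, all 53 genes fell (53 fell adjusted over the list alone), with a median of -0.75 (adjusted p = 2.61e-17, and adjusted p = 0.272 with an estimated correlation). The chromosome passenger incenp fell (-1.13) and the ubiquitin enzyme ube2c (-0.97). For S phase, 38 of the 41 genes fell, 1 rose and 2 did not pass (38 fell and 1 rose adjusted over the list alone), with a median of -0.84 (adjusted p = 4.05e-14, and adjusted p = 0.248 with an estimated correlation) and the replication genes gins3 and rpa2 at -1.56 ± 0.13 and -1.12 ± 0.094. Among ribosome biogenesis genes, 48 of the 52 members fell and 4 did not pass (48 fell adjusted over the list alone), with a median of -0.62 (adjusted p = 4.52e-19, and adjusted p = 0.234 with an estimated correlation). Ftsj3 fell (-1.26) and the nucleolar methyltransferase fbl (-0.83). Ribosomal protein genes fell in 77 of 79 (78 adjusted over the list alone), with a median of -0.34 (adjusted p = 1.20e-14, and adjusted p = 0.258 with an estimated correlation), and without DMSO replicate 2 the number was 60. Of protein folding and heat shock genes, 28 of the 39 members fell, 5 rose and 6 did not pass (28 fell and 5 rose adjusted over the list alone, camera adjusted p = 6.92e-08, and adjusted p = 0.234 with an estimated correlation). The endoplasmic reticulum chaperone hsp90b1 was at -1.18 ± 0.059 and pdia4 at -1.14 ± 0.055. Of tubulins, 14 of the 19 members fell, 1 rose and 4 did not pass (14 fell and 1 rose adjusted over the list alone, camera adjusted p = 5.91e-06, and adjusted p = 0.234 with an estimated correlation). Tubb4b was at -1.04 ± 0.072. Posterior hox genes fell in 12 of 16 and rose in 1 (12 and 1 adjusted over the list alone), with a median of -0.68 (adjusted p = 5.98e-05, and adjusted p = 0.272 with an estimated correlation). Hoxa13, which marks the most posterior tail, was at -1.76 ± 0.18 and hoxa9 at -0.97 ± 0.064. The FGF list was not called (adjusted p = 0.111, 0.0595 to 0.498 over its alternatives, fry adjusted p = 0.000266), and 12 of the 24 genes fell, 5 rose and 7 did not pass (12 fell and 5 rose adjusted over the list alone). Fgf16 fell (-1.77) and fgf2 rose by 3.5. For p53 targets, 17 of the 43 genes rose, 9 fell and 17 did not pass (17 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.0488, and adjusted p = 0.248 with an estimated correlation). Ccng1 was at 2.12 ± 0.090 and the translesion polymerase polk at 1.47 ± 0.093.

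For muscle, 35 of the 46 genes rose, 2 fell and 9 did not pass (35 rose and 2 fell adjusted over the list alone), with a median of 1.28 (adjusted p = 1.64e-10, and adjusted p = 0.272 with an estimated correlation). Creatine kinase ckm rose from 283 ± 42.5 to 889 ± 88.6 CPM and actc1 from 484 ± 64.9 to 1279 ± 131 CPM, against 5252 CPM at 0 hpa. Neuronal genes did not follow: 17 of the 47 members fell, 5 rose and 25 did not pass (17 fell and 5 rose adjusted over the list alone, camera adjusted p = 0.105; 0.0114 to 0.573 over its alternatives, fry adjusted p = 0.00463, and lower as a set without DMSO replicate 3 or echinomycin replicate 3, adjusted p = 0.0409 and 0.0287). Gap43, a growth cone protein, was at -1.7 ± 0.082 and mapt, which codes for tau, at -1.77 ± 0.23. In the notochord list, 18 of the 28 genes rose, 5 fell and 5 did not pass (18 rose and 5 fell adjusted over the list alone), with a median of 0.81 (adjusted p = 5.91e-06, and adjusted p = 0.248 with an estimated correlation). The cartilage collagens col2a1 and col9a2 rose by 1.29 and 2.22. Of matrix genes, 34 of the 56 members rose, 7 fell and 15 did not pass (34 rose and 7 fell adjusted over the list alone, camera adjusted p = 5.85e-06, and adjusted p = 0.272 with an estimated correlation). Elastin eln1 was at 2.35 ± 0.11 and thrombospondin thbs4 at 2.24 ± 0.17. Leukocyte genes were also higher, as 27 of the 40 members rose, 1 fell and 12 did not pass (28 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.13e-07, and adjusted p = 0.248 with an estimated correlation). The integrin itgb2 was at 1.31 ± 0.13 and csf3r at 0.98 ± 0.093. For endothelium, 23 of the 30 genes rose, 1 fell and 6 did not pass (24 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.91e-06, and adjusted p = 0.238 with an estimated correlation). Vwf was at 1.24 ± 0.11. Among pigment and neural crest genes, 17 of the 22 members rose, 4 fell and 1 did not pass (17 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.00135, and adjusted p = 0.248 with an estimated correlation). The endothelin receptor ednrb was at 2.44 ± 0.20. The adjusted p of genes named as changed was at most 0.00185, and 15 of the 38 lists were called, 8 up and 7 down. Other splits of these libraries into groups of 3 called 7 to 17 lists. With an estimated correlation camera called 0 lists (6 at an unadjusted p under 0.05), and fry called 29. Without a scaling factor the calls split into 6315 higher and 3441 lower, with upper-quartile factors into 5846 and 3907, and with limma on the deposited CPM 62.7% were higher. The p53 call ended without DMSO replicate 1 or echinomycin replicate 1 (adjusted p = 0.0601 and 0.0638; 0.0287 to 0.248 over its alternatives).

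**Figure D4:**
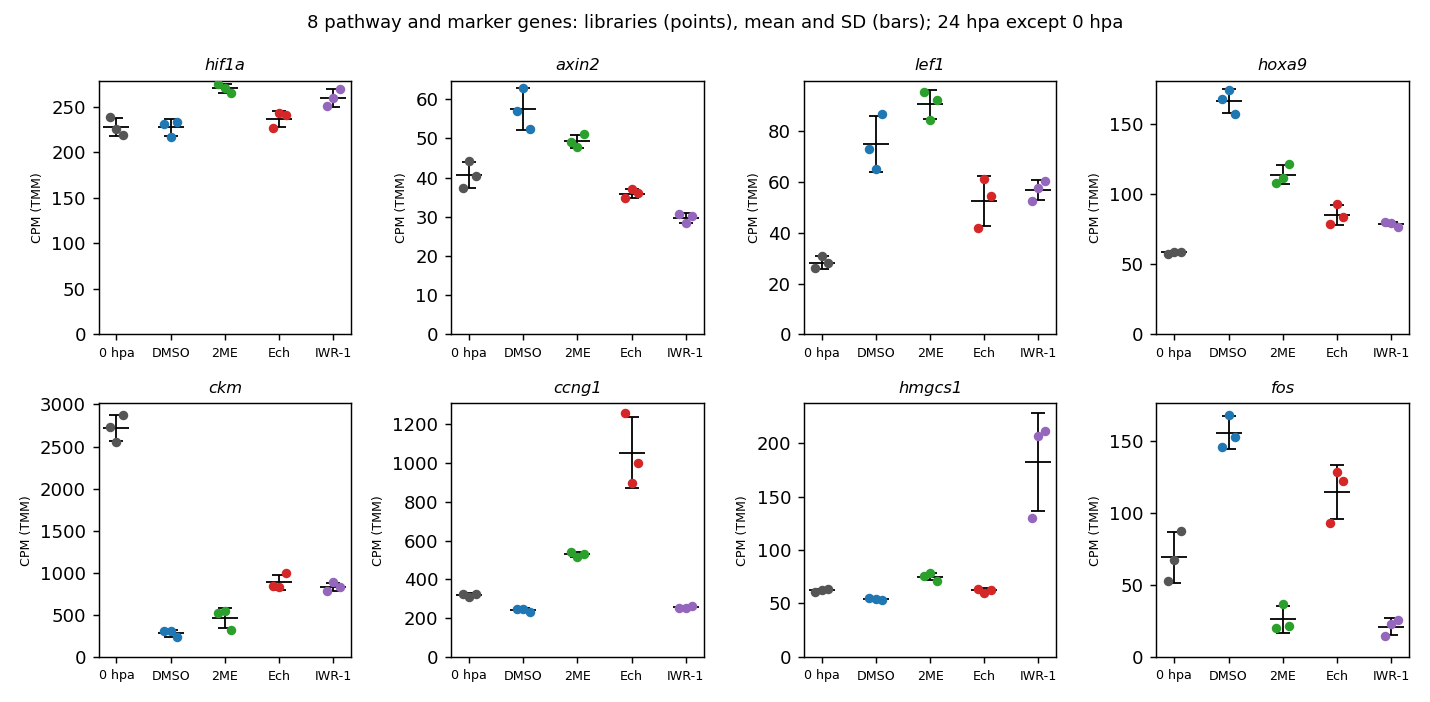
CPM of 8 genes (hif1a, axin2, lef1, hoxa9, ckm, ccng1, hmgcs1 and fos) in each of the 15 libraries, with points per library and black marks for the group mean ± SD. Axin2 has means of 40.7 CPM at 0 hpa, 57.4 with DMSO and 29.7 with IWR-1, and fos 156 with DMSO and 21 with IWR-1.

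IWR-1, a Wnt antagonist, was compared with DMSO. Camera called Wnt target, hox, tailbud and FGF lists lower and sterol synthesis, drug metabolism, muscle and glycolysis lists higher. Some lists share genes, so calls can overlap. Only central hox was called with an estimated correlation. The test called 7960 gene models, 3748 higher and 4212 lower; by 2-fold or more, 1117 were higher and 507 lower. The groups did not overlap in 7605 called models and in 52.2% of all tested models, against 10% by chance.

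In the Wnt target list, 13 of the 24 genes fell, 2 rose and 9 did not pass (13 fell and 3 rose adjusted over the list alone), with a median of -0.33 (adjusted p = 0.00407, and adjusted p = 0.318 with an estimated correlation). The counts were 5 higher and 8 lower without a scaling factor. Axin2 fell from 57.4 ± 5.33 to 29.7 ± 1.24 CPM (-0.95 ± 0.075), fgf8 (-2.1), the pseudoreceptor bambi (-1.45) and the Wnt inhibitor dkk1 (-1.11). Lef1 fell from 74.8 ± 11 to 56.9 ± 4.0 CPM (-0.40 ± 0.12, adjusted p = 0.0128), a call that ended without DMSO replicate 3 (log2 ratio -0.26, adjusted p = 0.0962) or IWR-1 replicate 1 (adjusted p = 0.0512; 0.00479 to 0.177 over its alternatives). Ctnnb1 fell (-0.13) (adjusted p = 0.0400, from 1416 ± 45.4 to 1293 ± 16.5 CPM), a call lost under most of its alternatives and turned to 0.028 without a scaling factor (0.0240 to 0.682; without DMSO replicate 1 the log2 ratio was -0.10, adjusted p = 0.173, without DMSO replicate 2 adjusted p = 0.118, and without IWR-1 replicate 1, 2 or 3 adjusted p = 0.0795, 0.0725 and 0.100). Hif1a rose by 0.19 (adjusted p = 0.00859), epas1 from 11.1 ± 0.98 to 23.1 ± 1.23 CPM (1.06 ± 0.14) and arnt by 0.18 (adjusted p = 0.0191; without DMSO replicate 2 or IWR-1 replicate 2 adjusted p = 0.0697 and 0.0581, and 0.000314 to 0.0697 over its alternatives). HIF1 targets were not called as a set (adjusted p = 0.0831, 0.0348 to 0.318 over its alternatives, fry adjusted p = 0.00433), and 16 of the 41 members rose, 7 fell and 18 did not pass (17 rose and 7 fell adjusted over the list alone). The matrix enzyme loxl2 was at 1.55 ± 0.13 and stc1 at -2.06 ± 0.19.

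The largest rise was in slc41a2 (gene16015), a magnesium transporter gene with 0 counts in all DMSO libraries, at least 404-fold higher (19.6 ± 13.9 CPM); other copies carry the symbol. Mgc108322 rose from 7.59 ± 2.01 to 707 ± 93.3 CPM (6.55 ± 0.16), the cytochrome P450 genes cyp2e1 and cyp2f1 from 3.54 ± 0.557 to 48.2 ± 13 CPM and 1.84 ± 0.592 to 13.1 ± 1.98 CPM, and papss2, which makes the sulfate donor for sulfotransferases, from 61.8 ± 9.19 to 487 ± 125 CPM (2.98 ± 0.16). Teddm1 rose by 3.41, the methyltransferase bhmt by 3.06 and the engulfment receptor megf10 by 2.75. Keratin genes were among the largest falls. Krt51, with 1 count over the group, was 977 times lower (counting interval 175 to 38600), krt53, with 3 counts, 136 times lower (46.0 to 661), krt12.2 fell from 13110.0 ± 1098 to 2799 ± 150.0 CPM (-2.23 ± 0.16) and krt78.1 from 415 ± 89.2 to 96.7 ± 1.79 CPM (-2.1 ± 0.14). Fos fell from 156 ± 11.6 to 21 ± 5.87 CPM (-2.89 ± 0.23), the ventral homeobox gene ventx2.2 from 6.15 ± 1.04 to 0.905 ± 0.144 CPM (-2.76 ± 0.23), lrat (-2.54) and the growth factor fgf20 from 6.07 ± 0.796 to 1.05 ± 0.357 CPM (-2.52 ± 0.31).

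Of central hox genes, 9 of the 11 members fell and 2 did not pass (9 fell adjusted over the list alone), with a median of -1.0 (adjusted p = 4.86e-05, and adjusted p = 0.0493 with an estimated correlation), the one call of the comparison that held with it. For posterior hox, 13 of the 16 genes fell and 3 did not pass (13 fell adjusted over the list alone), with a median of -1.02 (adjusted p = 4.57e-08, and adjusted p = 0.268 with an estimated correlation). Hoxa9 was at -1.08 ± 0.064, hoxc9 (gene27488) at -1.69 ± 0.12 and hoxb8 of the central group at -1.15 ± 0.17. In the tailbud list, 12 of the 25 genes fell, 3 rose and 10 did not pass (13 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.00413, and adjusted p = 0.294 with an estimated correlation). The ligands wnt5a and wnt5b were at -1.0 ± 0.098 and -0.66 ± 0.073. Among FGF genes, 13 of the 24 members fell, 5 rose and 6 did not pass (14 fell and 5 rose adjusted over the list alone, camera adjusted p = 0.00413, and adjusted p = 0.310 with an estimated correlation). Fgf16 was at -1.57 ± 0.13 and the receptor fgfr4 at -1.21 ± 0.10. For BMP and TGF-beta, 19 of the 34 genes fell, 7 rose and 8 did not pass (21 fell and 7 rose adjusted over the list alone, camera adjusted p = 0.00250, and adjusted p = 0.268 with an estimated correlation). Bmp2 was at -0.83 ± 0.076.

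In the sterol and lipid synthesis list, 22 of the 25 genes rose and 3 did not pass (22 rose adjusted over the list alone), with a median of 0.92 (adjusted p = 2.43e-14, and adjusted p = 0.294 with an estimated correlation). The sterol enzymes hmgcs1 and sqle rose by 1.76 and 2.14 and fatty acid synthase fasn by 2.21. Of drug and steroid metabolism genes, 10 of the 24 members rose and 14 did not pass (10 rose adjusted over the list alone, camera adjusted p = 0.00330, and adjusted p = 0.268 with an estimated correlation). Sult1a1 was at 2.43 ± 0.12 and cyp4b1 at 2.58 ± 0.13. For glycolysis, 12 of the 20 genes rose, 2 fell and 6 did not pass (13 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.00413, and adjusted p = 0.318 with an estimated correlation). The enolase eno1 was at 1.62 ± 0.10 and gapdh at 0.78 ± 0.10. Muscle genes rose in 34 of 46 (37 rose and 1 fell adjusted over the list alone), with a median of 1.18 (adjusted p = 7.53e-14, and adjusted p = 0.299 with an estimated correlation). Ckm rose from 283 ± 42.5 to 833 ± 49.6 CPM and the myogenic factor myf5 by 1.47. Beside muscle, 13 of the 30 endothelial genes rose, 2 fell and 15 did not pass (13 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00413, and adjusted p = 0.342 with an estimated correlation) and 12 of the 27 erythroid genes rose and 15 did not pass (14 rose adjusted over the list alone, camera adjusted p = 0.00413, and adjusted p = 0.683 with an estimated correlation). The neuron, leukocyte and p53 lists were not called (adjusted p = 0.522, 0.375 and 0.864). The p53 test leaned upward while its median was -0.015, which became 0.005 with RLE factors, and the neuron median of -0.10 became 0.056 without a factor. Of G2 and mitosis genes, 24 of the 53 members fell, 1 rose and 28 did not pass (25 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000842, and adjusted p = 0.683 with an estimated correlation). The ubiquitin enzyme ube2s was at -0.58 ± 0.072. The mitotic counts were 3 higher and 13 lower without a scaling factor. Ribosomal protein genes fell in all 79 (79 adjusted over the list alone), with a median of -0.42 (adjusted p = 1.43e-22, and adjusted p = 0.159 with an estimated correlation) and a share of counts of 7.46 to 8.15%. Genes named as changed had an adjusted p of at most 0.0400, and 20 of the 38 lists were called, 7 up and 13 down. Among lists that fry did not call were the erythroid and mitotic ones (adjusted p = 0.172 and 0.0610; 0.00245 to 0.683 and 0.000207 to 0.683 over their alternatives). Without a scaling factor the calls split into 5715 higher and 2296 lower, and with limma on the deposited CPM 71.1% were higher.

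The compounds were set against each other directly, at the doses used, which differ (5, 0.5 and 10 µM). A call with 1 compound and not with another was read as a difference only where this direct test called it. 2ME and echinomycin differed in 8301 gene models (4301 higher and 4000 lower with 2ME), 2ME and IWR-1 in 4235 (2083 and 2152), and echinomycin and IWR-1 in 6553 (3051 and 3502). Proliferation parted echinomycin from the others. Against echinomycin, 2ME had higher expression in all 53 mitotic genes (53 adjusted over the list alone; adjusted p = 3.07e-21, and adjusted p = 0.252 with an estimated correlation) and in 50 of 52 ribosome biogenesis genes, with 1 lower (51 and 1 adjusted over the list alone; adjusted p = 1.02e-25, and adjusted p = 0.132 with an estimated correlation). Echinomycin was lower than IWR-1 in 48 mitotic genes (50 adjusted over the list alone; adjusted p = 2.63e-15, and adjusted p = 0.256 with an estimated correlation). Leukocyte genes parted 2ME from the others, with 31 of 40 lower than with echinomycin (31 adjusted over the list alone; adjusted p = 4.36e-16, and adjusted p = 0.132 with an estimated correlation) and 25 lower than with IWR-1 (28 lower and 1 higher adjusted over the list alone; adjusted p = 5.24e-12, and adjusted p = 0.169 with an estimated correlation). Sterol synthesis genes parted IWR-1, with 22 of 25 lower with 2ME than with IWR-1 (23 adjusted over the list alone; adjusted p = 9.44e-17, and adjusted p = 0.169 with an estimated correlation) and 23 lower with echinomycin (23 adjusted over the list alone; adjusted p = 2.52e-14, and adjusted p = 0.223 with an estimated correlation). Notochord genes were higher with echinomycin than with IWR-1 in 20 of 28 and lower in 1 (20 and 1 adjusted over the list alone; adjusted p = 1.18e-10, and adjusted p = 0.128 with an estimated correlation).

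Of Wnt targets, 14 of 24 were higher and 1 lower with 2ME than with IWR-1 (16 and 1 adjusted over the list alone; adjusted p = 5.47e-08, and adjusted p = 0.163 with an estimated correlation), and with echinomycin 11 were higher and 4 lower (13 and 4; adjusted p = 0.0204, and adjusted p = 0.305 with an estimated correlation). The compounds given as Hif1a antagonists differed in HIF1 targets, 17 of 41 lower and 4 higher with 2ME (17 and 4 adjusted over the list alone; adjusted p = 0.00453, and adjusted p = 0.146 with an estimated correlation). Single genes also separated them. Gstp1 stood at 2182 ± 213 CPM with 2ME and 271 ± 12.9 with echinomycin, xa-1 at 122 ± 18.3 and 13.5 ± 1.76, and osgin1 was higher with 2ME by 3.21 on the log2 scale. The cartilage gene chad and the IGF-binding protein protease pappa2 were lower with 2ME than with echinomycin (-3.9 ± 0.16 and -3.76 ± 0.20) and than with IWR-1 (-2.15 ± 0.17 and -2.22 ± 0.21). Krt51 was 134 times higher with 2ME than with echinomycin (counting interval 45.6 to 654) and 420 times higher than with IWR-1 (74.9 to 16600). Dscaml1 and sh2d6 were higher with echinomycin than with IWR-1 (3.7 ± 0.16 and 3.88 ± 0.23), and mgc108322 and cyp2e1 were lower (-4.46 ± 0.14 and -3.05 ± 0.18). Slc41a2 (gene16015) had 0 counts with both 2ME and echinomycin and was at least 456-fold and at least 430-fold higher with IWR-1; DESeq2 did not call it (adjusted p = 0.0661 and 0.0517; 3.94e-09 to 0.0661 and 1.99e-09 to 0.0517 over its alternatives).

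Many genes moved in the same direction with different compounds. Against DMSO, 1264 gene models were higher and 1597 lower with all 3 compounds. Echinomycin and IWR-1 had the most calls in common, 2443 both higher and 2880 both lower, with 340 in opposite directions. Independent lists of these sizes would share 922 and 1136. For 2ME and IWR-1 the counts were 1807 and 2118 (524 and 697 if independent), with 143 opposite, and for 2ME and echinomycin 1519 and 1827 (648 and 840), with 617 opposite. Without DMSO replicate 2 the calls in the same direction went from 3925 to 2370 for 2ME and IWR-1, and from 3346 to 1927 for 2ME and echinomycin. All 3 compounds share the DMSO libraries. In 20 simulated sets of unchanged groups with a shared control, the calls in the same direction were at most 1. Few genes are called in unchanged groups, so that count was bound to be low. It gives no measure for compounds that each change many genes. Across genes, fold changes had r = 0.662 for echinomycin and IWR-1 (covariance 0.367, against 0.038 simulated), 0.585 for 2ME and IWR-1 (0.250 against 0.038) and 0.415 for 2ME and echinomycin (0.197 against 0.039), where simulated r was 0.508, 0.509 and 0.514. The differences of the covariances were 0.329, 0.212 and 0.158. The 3 controls cannot be split into sets of at least 2 libraries, and part of the excess may come from the shared DMSO libraries.

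The last question is whether a compound moved the genes of regeneration back towards 0 hpa. Of the 6056 gene models higher at 24 hpa with DMSO, echinomycin lowered 3201 (52.9%), IWR-1 2894 (47.8%) and 2ME 1923 (31.8%). Of the 5798 lower at 24 hpa, echinomycin raised 2718 (46.9%), IWR-1 2233 (38.5%) and 2ME 1485 (25.6%). Regeneration calls moved further in their own direction numbered 1248, 899 and 954. Opposed calls came to 5919, 5127 and 3408, the last falling to 2189 without DMSO replicate 2. In 20 simulated sets of unchanged compounds they were at most 1, a count again bound to be low. Of those higher at 24 hpa, 3650, 3885 and 4432 were also above 0 hpa with echinomycin, IWR-1 and 2ME. Of the regeneration calls in either direction, 543, 321 and 122 were called on the opposite side of 0 hpa with the compound. Across genes, the changes with each compound and in regeneration had r = -0.489 for echinomycin (covariance -0.479, simulated -0.038), -0.492 for IWR-1 (-0.434, simulated -0.039) and -0.356 for 2ME (-0.269, simulated -0.039), with simulated r of -0.109, -0.112 and -0.111. The covariances differed from the simulated ones by -0.441, -0.395 and -0.230. DMSO enters both sides of each comparison, and part of the excess may come from those shared libraries.

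**Figure D5:**
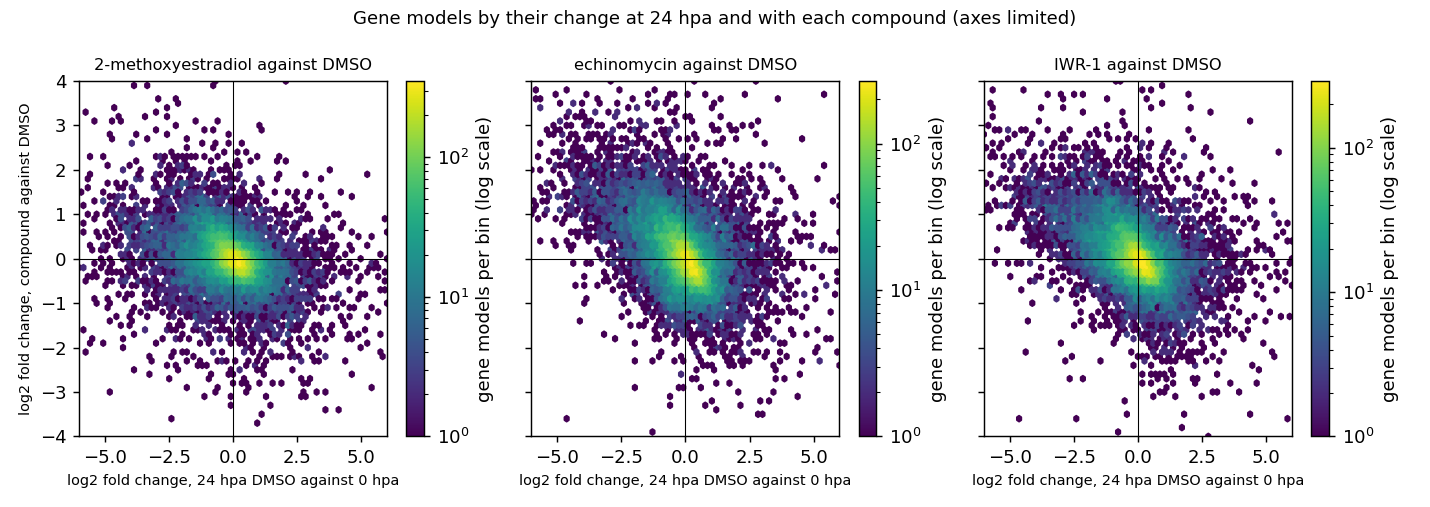
Log2 ratio with each compound against DMSO (vertical) and of DMSO at 24 hpa against 0 hpa (horizontal) for the 18823 tested gene models, coloured by the number of models per bin, with axes limited so that 96 (2ME), 105 (echinomycin) and 98 (IWR-1) models lie outside. Across genes r is -0.356, -0.489 and -0.492, against -0.111, -0.109 and -0.112 in simulated unchanged groups that share the DMSO libraries.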

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

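No result was singled out by the rules for an outlying sample (groups of 3 are not tested), for opposite effects between groups or for a signal outside the main measurement. The patterns weighed here were picked after the results were seen, and so were their tests, except the test of short transcripts, whose interval was also added after.

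Muscle genes were higher with echinomycin and IWR-1 than with DMSO, with actc1 at 5252 CPM at 0 hpa, 484 with DMSO, 1279.5 with echinomycin and 1119.8 with IWR-1, and tpm1 at 3399, 925, 1252 and 1009. Carry-over of tissue from anterior to the amputation plane would raise nerve genes by the same share of the distance to 0 hpa, but the highest share of neural genes was 0.050 with echinomycin and 0.048 with IWR-1, against 0.116 to 0.165 and 0.110 to 0.137 for muscle (41 of 46 muscle and 59 of 74 neural members). Carry-over and more muscle cells or transcripts stay open, since endothelial genes rose by 0.251 to 0.354 of that distance with echinomycin and 0.077 to 0.122 with IWR-1 and pigment cell genes by 0.188 to 0.290 with echinomycin (with IWR-1 by 0.036 to 0.069, below muscle), and 2ME moved neural genes by -0.118 to -0.069, so an effect on nerve genes could hide such tissue. Muscle medians exceeded neuron medians by at least 1.005 with echinomycin and 1.055 with IWR-1, against -0.203 to 0.074 with DMSO. That cannot test a smaller share of other cell types, which may include neurons. With DMSO 38 of 46 muscle and 33 of 47 neuron markers were at 1 CPM or more, with 1 and 2 in another list. Dpysl3 was at 77.8, 66.3 and 44.9 CPM and mapt at 72, 21.1 and 30.5 with DMSO, echinomycin and IWR-1.

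Posterior hox genes were lower with all 3 compounds than with DMSO. Carry-over of tissue from anterior to the amputation plane would move them by the same share as muscle genes, but their lowest share of the distance to 0 hpa was 0.659 (up to 1.084, from 12 of 16 members), against at most 0.165 for muscle and 0.354 for endothelium. Scaling between libraries would move them like all genes, but without a scaling factor their upper quartile relative to the median of all genes was at most -0.419 with each compound. A response of these genes to the compounds, by whatever route, may account for the pattern and was not tested.

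Ribosomal protein genes were lower with all 3 compounds than with DMSO. Scaling between libraries would move them like all genes, but without a scaling factor their upper quartile relative to the median of all genes was at most -0.301. An aberrant DMSO library would end the calls when left out, but at least 60 of 79 stayed lower with any DMSO library left out, the fewest with echinomycin without DMSO replicate 2. Short transcripts counted less with the compounds cannot be told apart from an effect on these genes. Other genes matched on length and abundance also fell, though longer (median 878 against 719) and scarcer (551 against 957 CPM). Medians were -0.243, -0.263 and -0.257 for 2ME, echinomycin and IWR-1 (95% intervals -0.309 to -0.194, -0.322 to -0.203 and -0.370 to -0.158). These intervals reach the upper quartile of ribosomal protein genes for echinomycin (-0.289) and IWR-1 (-0.370), not 2ME (-0.396). A response to the compounds also stays open.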

How the results depend on the processing

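Library size only, with no scaling factor, was the alternative chosen after the data were seen, and the others were planned. Of 443 results on single genes, 6896 values under the alternatives kept direction and side of the threshold, 16 passed it, 51 no longer did and 7 changed direction. Of 86 list tests these numbers were 749, 12, 97 and 2, and 70 of the 97 came from camera with an estimated correlation.

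With the 2-fold threshold the counts of changed genes were 4372 at 24 hpa, 874 with 2ME, 2259 with echinomycin and 1624 with IWR-1, since that threshold asks for a larger change. Camera with an estimated correlation called 1, 0, 0 and 1 lists (10, 6, 6 and 6 at an unadjusted p under 0.05) and fry 37, 19, 29 and 23, and the cause was not tested. The sign of hif1a at 24 hpa turned to 0.012 without a low-count filter, 0.013 with library size only and 0.011 with limma on the deposited CPM, and ranged from -0.048 (without 0 hpa replicate 3) to 0.013 (without DMSO replicate 2). That of ctnnb1 with IWR-1 turned to 0.028 with library size only and 0.029 with limma. The p53 list with IWR-1 turned in fry (adjusted p = 0.442). The HIF1 target list with 2ME had an adjusted p of 0.582 (without DMSO replicate 1) to 0.951 (without DMSO replicate 2, where it turned). The cause of these turns was not tested.

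Leaving out 1 library gave 3766 to 5366 changed genes with 2ME, 1927 to 3394 calls in the same direction for 2ME and echinomycin, 2370 to 3932 for 2ME and IWR-1, and 2189 to 3259 regeneration calls opposed by 2ME, each lowest without DMSO replicate 2. Some log2 ratios moved by 1 or more, such as fndc7 with echinomycin to 2.15 (without echinomycin replicate 1) and hba2 at 24 hpa to -5.58 (without 0 hpa replicate 1). The other counts stayed within 1.5 times their value with all libraries.

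Replicate numbers do not pair the samples: residuals of samples with the same number had correlations across genes of -0.144 to 0.126 (median 0 over 30 pairs, 2 of them above 0.1), and 4 of 15 libraries were closest to their own number. With that number as a block the counts of changed genes were 11678, 5446, 9510 and 7683, and of the named genes the block ended the call of ctnnb1 with IWR-1 (adjusted p = 0.0625). Counting transcripts was not run, since each gene model has 1. The 7 simulated comparisons each had 200 genes changed, 50 per ratio. EdgeR called 12 to 28% at the smallest ratio, 50 to 70% at 1.5-fold, 78 to 88% at 2-fold and 94 to 100% at 4-fold. Far more genes were called in the data, where rates may differ. Depth, number of libraries and spread were not varied.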

Other observations

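Further lists were called, with values given here alone. Among oxidative phosphorylation genes, 34 of the 48 genes fell and 14 did not pass (34 fell adjusted over the list alone), with a median of -0.36 (adjusted p = 6.99e-08, and adjusted p = 0.488 with an estimated correlation) at 24 hpa. With 2ME 21 of the 48 genes fell, 1 rose and 26 did not pass (25 fell and 1 rose adjusted over the list alone), with a median of -0.18 (adjusted p = 6.98e-05, and adjusted p = 0.681 with an estimated correlation) (fry adjusted p = 0.0776, 6.58e-07 to 0.681 over the alternatives), and the counts turned to 6 higher and 1 lower without a scaling factor. With echinomycin 28 of the 48 genes fell and 20 did not pass (30 fell adjusted over the list alone), with a median of -0.22 (adjusted p = 2.37e-05, and adjusted p = 0.558 with an estimated correlation), and the counts were 0 higher and 9 lower with upper-quartile factors and 2 higher and 7 lower without a factor. With IWR-1 18 of the 48 genes fell, 1 rose and 29 did not pass (17 fell and 1 rose adjusted over the list alone), with a median of -0.16 (adjusted p = 0.00354, and adjusted p = 0.718 with an estimated correlation), and without a scaling factor the median became 0.004 and the counts 9 higher and 1 lower (fry adjusted p = 0.0989, limma 0.355, without DMSO replicate 2 adjusted p = 0.118, 0.000150 to 0.718 over the alternatives). Of anterior hox genes, 6 of the 11 members fell and 5 did not pass (6 fell and 1 rose adjusted over the list alone) with 2ME (adjusted p = 0.00246, and adjusted p = 0.164 with an estimated correlation), and with IWR-1 6 of the 11 members fell, 1 rose and 4 did not pass (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.268 with an estimated correlation). Sterol and lipid synthesis genes moved up at 24 hpa, where 13 of the 25 members rose and 12 did not pass (12 rose adjusted over the list alone, camera adjusted p = 0.0325, and adjusted p = 0.660 with an estimated correlation; limma adjusted p = 0.0598, 0.0189 to 0.660 over the alternatives), and with 2ME 8 of the 25 members rose and 17 did not pass (8 rose adjusted over the list alone, camera adjusted p = 0.00214, and adjusted p = 0.681 with an estimated correlation; fry adjusted p = 0.177, 0.000463 to 0.681 over the alternatives).

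For multiciliated cells, ionocytes and goblet cells, 23 of the 33 genes fell, 3 rose and 7 did not pass (24 fell and 3 rose adjusted over the list alone) at 24 hpa (adjusted p = 0.000103, and adjusted p = 0.165 with an estimated correlation) and 13 of the 33 genes rose, 3 fell and 17 did not pass (13 rose and 4 fell adjusted over the list alone) with 2ME (adjusted p = 0.000388, and adjusted p = 0.265 with an estimated correlation). In the oxidative stress list, 20 of the 38 genes rose, 7 fell and 11 did not pass (21 rose and 8 fell adjusted over the list alone) at 24 hpa (adjusted p = 0.00605, and adjusted p = 0.329 with an estimated correlation). With 2ME 15 of the 38 genes rose, 7 fell and 16 did not pass (15 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0175, and adjusted p = 0.509 with an estimated correlation), where the test was upward, the median -0.019 and the median without a scaling factor 0.12. S phase genes were lower at 24 hpa, where 22 of the 41 members fell, 2 rose and 17 did not pass (22 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.00133, and adjusted p = 0.586 with an estimated correlation), and with IWR-1 17 of the 41 members fell and 24 did not pass (16 fell adjusted over the list alone, camera adjusted p = 0.00687, and adjusted p = 0.683 with an estimated correlation; fry adjusted p = 0.0847, 0.00294 to 0.683 over the alternatives), or 1 higher and 6 lower without a scaling factor. With IWR-1 26 of the 56 matrix genes rose, 10 fell and 20 did not pass (26 rose and 11 fell adjusted over the list alone, camera adjusted p = 0.0143, and adjusted p = 0.553 with an estimated correlation) and 11 of the 19 tubulins fell, 1 rose and 7 did not pass (12 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000830, and adjusted p = 0.281 with an estimated correlation). Ribosome biogenesis genes with IWR-1 had a median of -0.15, or 0.012 without a scaling factor (counts 10 higher and 10 lower), and 25 of the 52 members fell, 2 rose and 25 did not pass (25 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.00150, and adjusted p = 0.553 with an estimated correlation; limma adjusted p = 0.0829, 0.000360 to 0.553 over the alternatives). Protein folding genes had -0.12 and 0.043, and 15 of the 39 members fell, 8 rose and 16 did not pass (15 fell and 9 rose adjusted over the list alone, camera adjusted p = 0.0200, and adjusted p = 0.397 with an estimated correlation; limma adjusted p = 0.0820, without IWR-1 replicate 1 adjusted p = 0.0507, 0.00943 to 0.397 over the alternatives).

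The counts were set against other splits of the same libraries into groups of 3, tests planned before the results were seen. The splits, 10 per comparison and 19 per overlap, are too few for a share under 0.05. For changed genes 1 of 10 splits, the real one, gave as many in each comparison (values above). The highest other was 1 for IWR-1 and 0 for the others. For called lists, 2 of 10 splits gave as many at 24 hpa (22, and 22 in another split), 1 with 2ME (15, highest other 13), 3 with echinomycin (15, highest other 17) and 1 with IWR-1 (20, highest other 19). For calls in the same direction 1 of 19 splits gave as many (3346 for 2ME and echinomycin, 3925 for 2ME and IWR-1, 5323 for echinomycin and IWR-1). For opposed regeneration calls it was 1 of 10 (3408, 5919 and 5127 for 2ME, echinomycin and IWR-1). Other splits called at most 1 gene for the split compound, so both counts could not exceed 1 there.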
